A study of Sus scrofa with 4 samples.

How the data were processed

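Material of pig (Sus scrofa) blastocysts, RNA per the labels, was hybridised to 4 two-colour EMPV1 arrays, a porcine oligonucleotide design. Per the labels, each array set a pool of 10 blastocysts from oocytes exposed to a high level of non-esterified fatty acids (NEFA) against a pool of 10 control blastocysts, and pools were collected on days 7 and 8. The labels place the high NEFA pool in Cy3 on replicates 1 and 2 and in Cy5 on replicates 3 and 4. They call the arrays biological replicates, so the 4 pools of each kind were taken as separate samples, and no array was left out. Nothing in the labels says that the replicates came from separate sows or collections, and p-values measure the spread between these pools. The labels name total RNA as the molecule and expression profiling as the study type, while their extraction and labelling protocols describe the digestion of genomic DNA by methylation-sensitive enzymes. The report gives intensities of ribosomal protein probes and of other gene lists. These do not settle which of the 2 was hybridised.

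The deposited scanner files hold, per the file headers, the median and mean pixel intensity of each spot and of its local background at 532 nm (Cy3) and 635 nm (Cy5), with a 0 or 1 mark for spots to be ignored. These values were neither background-subtracted nor normalized. The image software is not given in the sources used here. Each array had 45220 spots, of which 43794 held EMPV1 probes and 153 were negative controls. The number of marked spots was 60, 21, 17 and 17 on replicates 1 to 4, and marked spots were left out. The authors' series matrix holds 1 column of log2 ratios per array, whose scale and direction are not stated. Set against the scanner files by spot number, each column followed log2 of Cy5 over Cy3 of the median intensities after subtraction of the median background, loess and quantile normalization, with a correlation over 43794 spots between 0.984 and 0.995. Its column medians were 0.0022, 0.0083, 0.0088 and 0.016. The column was not turned by dye, and it served as an alternative only. The submitters' processing notes name limma, with no version and no settings.

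From the median intensities, background was corrected with normexp and an offset of 50, and each array was normalized by loess with control spots at weight 0, using limma 3.58.1 in R 4.3.3 with statmod 1.5.0. No scaling between arrays was applied. A probe counted as above background in a channel when its foreground exceeded the mean of the negative control spots of that array and channel by more than 2 SD. The 24524 probes above background in at least 4 of the 8 channel measurements were tested. For each probe, limma fitted log2 of Cy5 over Cy3 with 1 coefficient for exposure, signed by the dye of the high NEFA pool, and an intercept for the dye effect, followed by empirical Bayes moderation without trend or robust prior. The threshold was a two-sided Benjamini-Hochberg adjusted p of 0.05. A looser, nominal threshold was an unadjusted p of 0.05 with at least a 1.5-fold difference. With 4 arrays and 2 coefficients, 2 residual degrees of freedom remained, and moderation added 7.87. The median SE of the log2 ratio was 0.13, and the number of arrays limits the precision.

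Gene symbols came from the platform table, keyed by spot number. Of the probes, 13146 had 1 symbol, 0 had several and 30648 had none. A RefSeq gene table served to update 201 older symbols. No genome build is named in the sources used here, and no coordinates are given. A gene was represented by its probe of highest mean log2 intensity, which gave 6226 genes with a tested probe, 6213 of them with a value on every array.

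Before the data were examined, 23 gene lists, the test of each comparison, the alternatives and the rule for named genes were fixed. The lists covered fatty acid and sterol metabolism, stress, energy metabolism, blastocyst lineages, epithelial junctions, DNA methylation, imprinting, growth factor and immune signalling, the cell cycle, protein folding, ribosomal proteins, markers of granulosa cells and oocytes, and sex-linked markers. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, whose directional p asks whether the genes move on balance one way and whose mixed p asks whether they differ in either direction. The genes named are those past the adjusted threshold with the same direction in all 4 arrays, up to 12 per direction. Where fewer pass, the places go to genes of smallest unadjusted p with the same direction in all 4 arrays and at least a 1.5-fold difference. The 2 members of smallest p in each list, every measured sex-linked marker and the 3 brightest members of the granulosa and oocyte lists are named as well. The 5 probes with an adjusted p under 0.1 were named after their values were seen.

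The alternatives were no background correction, plain subtraction, an offset of 16, median centring, Aquantile scaling, no filter, a filter of all 8 channels, no dye term, a trended robust prior, array weights, each replicate left out in turn, the authors' matrix values, the mean of all probes of a gene, the other list tests and an adjusted threshold of 0.1. Mean pixel intensity in place of the median, and 1 background value per array and channel (the median over spots) in place of each spot's local background, were chosen after seeing the data. Slide and scan dates are not given in the sources used here, and no such block was fitted.

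The fit was tested on simulated data for 24524 probes with the fitted dye effects and variances drawn from the fitted prior, in 20 runs. Residuals were drawn independently for each probe. With no exposure effect, 0 probes passed the adjusted threshold in any run and 71.5 passed the nominal threshold on average, with 81 in the highest run. With 200 changed probes, the share recovered was 17.9% at 1.5-fold, 89.1% at 2-fold, 99.7% at 3-fold and 100% at 4-fold, with 8.2 false calls on average. A first version of the simulation drew residuals with the moderated variance of each probe. Without any exposure effect it gave 1.75 probes past the adjusted threshold and 14.9 past the nominal threshold on average, and it recovered 61.3% at 1.5-fold and 99.9% at 2-fold. The variance model was replaced after these calls without an effect were seen. On 6213 simulated genes, camera called 3 of 100 unshifted lists of 15 genes at an unadjusted p under 0.05 and 100 of 100 lists shifted by 0.3 on the log2 scale. The simulated genes were independent of each other. In the data the estimated correlation reached 0.56 for ribosomal proteins and 0.34 for heat shock genes, so these shares do not carry over to such lists.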

Results

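Per its labels, the series compared gene expression in pig blastocysts from oocytes exposed to a high level of non-esterified fatty acids with that in control blastocysts. Non-esterified fatty acids (NEFA) are the free fatty acids that circulate in blood when fat stores are mobilised. The title also names a co-culture with a monolayer of GCs, an abbreviation the labels do not spell out, and the labels do not say whether both kinds of pool had it. The data comprised 4 arrays, each with 1 high NEFA pool and 1 control pool of 10 blastocysts, with the dyes exchanged between replicates 1 and 2 and replicates 3 and 4. The share of probes above background was 57.1%, 58.6%, 50% and 50.2% in the high NEFA channel of replicates 1 to 4, and 51.2%, 49.0%, 60.2% and 60.3% in the control channel. The higher share lay in Cy3 on every array. Median probe intensity was 332 to 397 in Cy3 and 202 to 247 in Cy5, against negative control means of 241 to 303 and 148 to 178. All ratios below are log2 of high NEFA over control, so that positive values are higher in the high NEFA pools.

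Probes for ribosomal proteins were among the brightest. Of 48 probes for cytosolic ribosomal proteins, which are among the most abundant messenger RNAs of growing cells, 41 lay in the top 10% of mean log2 intensity. That is 85.4%, with an exact 95% interval of 72.2% to 93.9%, against 10.0% of all probes by construction. The interval takes the 48 probes as independent, although they stand for 36 genes measured on the same arrays. The median log2 intensity was 15.21 for the ribosomal protein probes and 7.85 for all probes. Ribosomal protein genes have many processed pseudogenes in mammalian genomes, so these values do not by themselves separate RNA from digested genomic DNA. Median log2 intensity was 13.77 for tested oxidative phosphorylation and 13.11 for heat shock genes, 9.69 for glycolysis, 8.09 for granulosa and 8.02 for oocyte genes. All 17 oxidative phosphorylation genes on the array were above background in all 8 channels, against 4 of 19 oocyte and 5 of 19 granulosa genes. Whether genes of the brighter lists also have processed pseudogenes was not examined. Such differences between lists therefore do not separate RNA from genomic DNA either, and the material itself was not tested. Had genomic DNA been hybridised, as the protocols describe, the ratios below would not be transcript levels. Intensities spanned 27.4-fold from the 5th to the 95th percentile of probes.

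No gene passed the adjusted threshold between high NEFA and control blastocysts. In the limma fit, 0 of 24524 probes had an adjusted p under 0.05, and the smallest adjusted p was 0.0934. At an unadjusted p under 0.05 there were 1573 probes (6.41%), 778 higher and 795 lower in the high NEFA pools. Simulated arrays without any exposure effect gave 1233.7 such probes on average with variances drawn from the fitted prior and 1196 with the moderated variance of each probe. The nominal threshold took 88 probes, 53 higher and 35 lower, where these simulations gave 71.5 and 14.9 on average and 81 and 22 in their highest run. The first of these simulations was adopted after the second had been seen. The simulated probes were independent of each other, so the runs do not show how widely counts vary on real arrays. On the real arrays, the 2 other splits that part the dyes evenly gave 973 and 1073 probes at an unadjusted p under 0.05. They gave 77 and 108 past the nominal threshold. The median probe had a 95% interval of 0.30 on the log2 scale to either side of its estimate, a 1.23-fold difference, and the same design recovered 89.1% of simulated 2-fold changes and 17.9% of 1.5-fold changes (99.9% and 61.3% with moderated variances). Leaving out 1 array made calls appear: 79 probes passed without replicate 1, 76 without replicate 2, 36 without replicate 3 and 22 without replicate 4. With 1 background per array and channel, 64 probes passed the nominal threshold, 36 of them among the 88.

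By size and direction, 7 genes met the rule for named genes, and none of them passed the adjusted threshold. TET1, a dioxygenase that oxidises 5-methylcytosine in DNA, was higher in all 4 high NEFA pools, with ratios of 0.89, 1.06, 0.26 and 0.53 on replicates 1 to 4 and a fitted ratio of 0.68 ± 0.13 (SE, n = 4). Its adjusted p was 0.497 and its 95% interval 0.40 to 0.97. CD109, a membrane-anchored glycoprotein that binds transforming growth factor beta, had a ratio of 0.64 ± 0.17 (SE), from 0.11 to 1.35 over the arrays. On the lower side, OAS1, an interferon-induced enzyme that senses double-stranded RNA, had the largest difference, with a ratio of -0.93 ± 0.25 and array values of -1.84, -0.36, -0.15 and -1.38. MED1, a subunit of the Mediator complex that contacts nuclear receptors, had a ratio of -0.74 ± 0.15, and ICAM1, a leukocyte adhesion molecule, of -0.65 ± 0.14. The adjusted p of CD109, OAS1, MED1 and ICAM1 was 0.764, 0.764, 0.648 and 0.725. KCNK3, a potassium channel, had 0.72 ± 0.22 and DNAJB4, a heat shock protein 40 family member, -0.69 ± 0.14. With 1 background per array and channel, KCNK3 had 0.12 ± 0.16 and DNAJB4 -0.15 ± 0.14, while TET1, CD109, OAS1, MED1 and ICAM1 had 0.71, 0.69, -0.99, -0.79 and -0.70. With mean pixel intensity in place of the median, the ratios were 0.50 ± 0.04 for TET1, 0.37 ± 0.13 for CD109, -0.65 ± 0.26 for OAS1, -0.43 ± 0.14 for MED1, -0.42 ± 0.10 for ICAM1, 0.20 ± 0.03 for KCNK3 and 0.14 ± 0.06 for DNAJB4. SE with mean pixel intensity, here and below, come from a fit with its own moderated variances and are not directly comparable with the others. None of these genes passed the adjusted threshold in that fit. With 1 array left out, some passed the adjusted threshold. These were OAS1 without replicate 2 (ratio -1.30) or 3 (-1.24), KCNK3 without replicate 2 (0.96) or 3 (1.04), MED1 without replicate 4 (-0.95) and TET1 without replicate 1 (0.73). In each case the array left out had the smaller ratio of its dye orientation. Such fits leave 1 array alone in that orientation, and simulated arrays without effect then gave up to 17 calls (29 with moderated variances). The KCNK3 probe was above background in 2 of the 4 high NEFA and 2 of the 4 control channels.

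**Figure D1:**
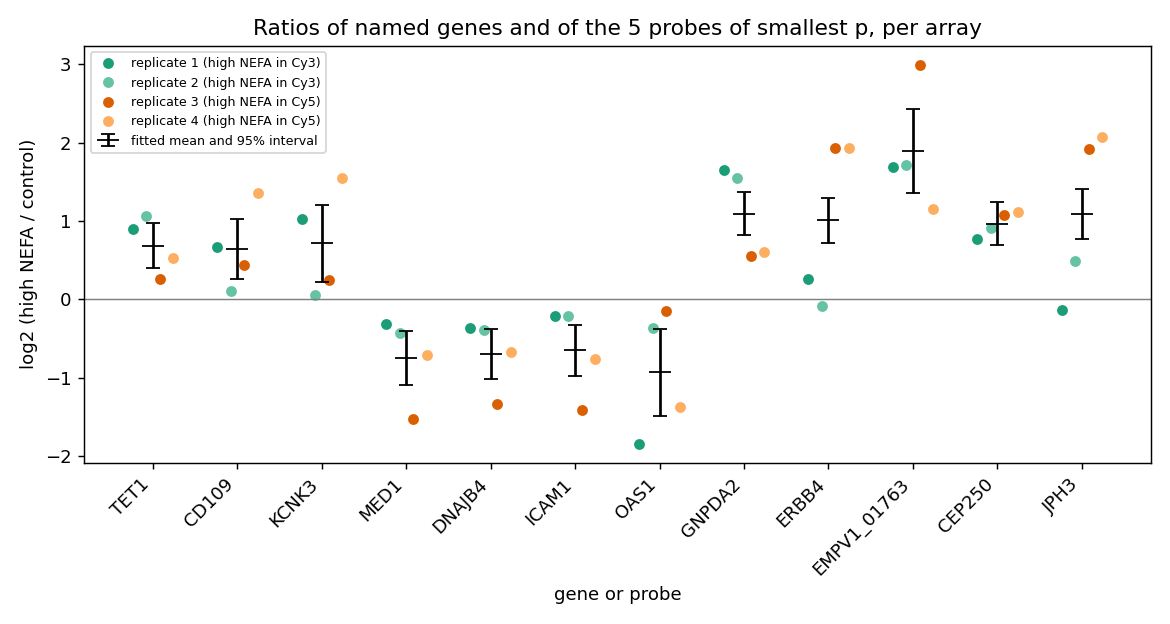
Log2 ratio of high NEFA over control on each of the 4 arrays (points) with the fitted mean and its 95% interval (bars), for the 7 genes that met the rule and for 5 probes chosen after their values were seen. OAS1 ranges from -1.84 to -0.15 and TET1 from 0.26 to 1.06 over the arrays.

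The 5 probes of smallest p all had a positive fitted ratio at an adjusted p of 0.0934, and were chosen after their values were seen. They were GNPDA2, an enzyme of glucosamine 6-phosphate metabolism (1.09 ± 0.12), ERBB4, a receptor tyrosine kinase of the epidermal growth factor receptor family (1.01 ± 0.13), CEP250, a centrosome linker protein (0.97 ± 0.12), JPH3, a junctional membrane protein (1.09 ± 0.14), and the unnamed probe EMPV1_01763 (1.89 ± 0.24). With 1 background per array and channel these ratios were 0.08 ± 0.14, 0.16 ± 0.14, 0.06 ± 0.14, 0.18 ± 0.14 and 0.08 ± 0.15. With mean pixel intensity of spot and local background they were -0.04 ± 0.08, 0.68 ± 0.06, 0.38 ± 0.05, 0.53 ± 0.15 and 0.68 ± 0.17, in the same order. The mean local background around the 5 spots was 73.2, 57.2, 48, 62.5 and 89.2 in the high NEFA channels and 212, 234, 212, 237 and 422 in the control channels, in the order GNPDA2, ERBB4, CEP250, JPH3 and EMPV1_01763. For GNPDA2 the raised control background lay in Cy5 of replicates 1 and 2, at 337 and 387. For ERBB4, CEP250 and JPH3 it lay in Cy3 of replicates 3 and 4, at 370 to 470. A second tested probe had a ratio of -0.01 ± 0.13 for GNPDA2 and 0.05 ± 0.13 for CEP250. On replicates 1 to 4, ERBB4 had 0.25, -0.08, 1.93 and 1.93, and JPH3 had -0.13, 0.49, 1.91 and 2.07. GNPDA2 and ERBB4 were above background in 3 of 4 high NEFA and 2 of 4 control channels. CEP250 was so in 2 of 4 channels of each kind, JPH3 in 3 of 4 of each, and EMPV1_01763 in 3 of 4 high NEFA and 4 of 4 control channels.

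**Figure D2:**
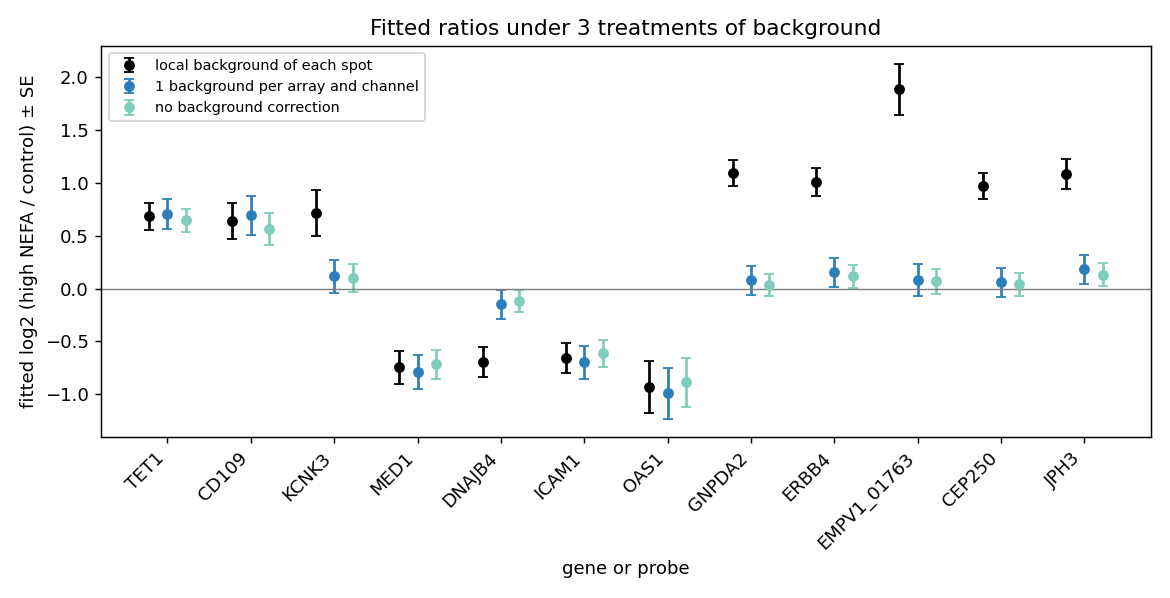
Fitted log2 ratio of high NEFA over control ± SE for the same genes and probes, with each spot's local background, with 1 background per array and channel, and with no background correction. TET1 stays between 0.65 and 0.71, and GNPDA2 moves from 1.09 to 0.08 and 0.03.

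By camera, trophectoderm had the smallest p of the lists, and no list passed. Across 23 lists, 0 had an adjusted p under 0.05 by camera, and 3 had an unadjusted p under 0.05: trophectoderm, interferon response, and tight junctions with blastocoel transport. The directional test of fry gave 0 lists past the adjusted threshold, with the smallest p for insulin and growth factor signalling (0.0071) and for apoptosis and p53 (0.0081), each at an adjusted p of 0.0928. None of the 315 listed genes tested passed over all probes. Adjustment over a list alone, given below, does not account for there being 23 lists and is the weaker criterion. Of 10 tested trophectoderm genes, which mark the outer layer of the blastocyst that forms the placenta, 8 were higher in the high NEFA pools, with a median ratio of 0.08 and an adjusted p of 0.0618 (adjusted p = 0.822 with an estimated correlation). The estimated test rests on 2 residual degrees of freedom, so its p rises even at a low correlation. For the pluripotency list, estimated at -0.05, the unadjusted camera p went from 0.160 to 0.287. The value of 0.822 therefore does not show that correlation between genes removes a shift. Without replicate 2 the trophectoderm median was 0.21. The homeobox gene DLX3 had 0.57 ± 0.13 and passed when adjusted over the list alone, as the only one of the 10 members. It was above background in 2 of 4 channels of each kind of pool and had 0.19 ± 0.14 with 1 background per array and channel and 0.09 ± 0.10 with mean pixel intensity. TFAP2C, a trophectoderm transcription factor, had 0.37 ± 0.15, GATA3 0.31 ± 0.13 and DAB2 0.28 ± 0.12. The array values of TFAP2C were 1.11, 0.35, 0.05 and -0.03 on replicates 1 to 4. Of 16 junction and transport genes, 13 were higher, with a median of 0.08 and an adjusted p of 0.228 (adjusted p = 0.822 with an estimated correlation). The desmosomal plakophilin PKP2, at -0.31 ± 0.13, and the water channel AQP9, at 0.22 ± 0.13, had the smallest p, and 0 members passed when adjusted over the list alone.

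Among 6 tested pluripotency genes, 4 were higher and 2 lower, with a median of 0.10 and an adjusted p of 0.678. LIN28A, an RNA-binding repressor of let-7 maturation, had 0.40 ± 0.13, UTF1 0.36 ± 0.13 and SOX15 -0.53 ± 0.19. These 3 passed when adjusted over the list alone, each at 0.0430. SOX15 was above background in 2 of 4 channels of each kind and had -0.28 ± 0.14 with 1 background per array and channel and 0.11 ± 0.16 with mean pixel intensity, where LIN28A had 0.22 ± 0.09. The array values of SOX15 were -1.16, 0.08, -0.61 and -0.45 on replicates 1 to 4, and its ratio was -0.84 without replicate 2. The 11 primitive endoderm genes had a median of -0.01, with 5 higher and 6 lower (adjusted p 0.678). The basement membrane chain LAMB1 had -0.35 ± 0.15 and APOA1 -0.35 ± 0.17.

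The interferon response list did not pass. Of 10 genes tested, 7 were lower and 3 higher, with a median of -0.12, a mean of -0.20 and an adjusted p of 0.104 (adjusted p = 0.822 with an estimated correlation). OAS1, at -0.93 ± 0.25, and OAS2, at -0.42 ± 0.13, both encode 2'-5'-oligoadenylate synthetases and passed when adjusted over the list alone, at 0.0388 and 0.0405. OAS2 was above background in 2 of 4 high NEFA and 4 of 4 control channels and had -0.02 ± 0.03 with mean pixel intensity. The other 8 members, among them IRF7 (-0.30 ± 0.14), did not pass over the list. Inflammation genes had a median of 0.01, with 7 of 14 higher (adjusted p 0.678), and IL6ST, the shared receptor subunit of interleukin 6 type cytokines, had 0.54 ± 0.15 and MYD88 0.17 ± 0.13. With 1 background per array and channel, IL6ST had 0.32 ± 0.14.

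Fatty acid metabolism, the process closest to the exposure, gave no list past the threshold. Of 19 fatty acid oxidation genes and targets of peroxisome proliferator-activated receptors, 9 were higher and 10 lower, with a median of -0.01 and an adjusted p of 0.775. ETFDH, which passes electrons from fatty acid oxidation to ubiquinone, was lower on all 4 arrays at -0.46 ± 0.14, and ACADL, an acyl-CoA dehydrogenase, had 0.40 ± 0.13. With mean pixel intensity these were -0.11 ± 0.07 and 0.85 ± 0.04. Of 16 lipid droplet and lipolysis genes, 10 were higher, with a median of 0.07 (adjusted p 0.678), and DGAT1, which makes triglyceride, had 0.29 ± 0.12 and CIDEB -0.29 ± 0.13. The 14 sterol and fatty acid synthesis genes had a median of 0.02 (adjusted p 0.678), with SQLE at -0.44 ± 0.13 and HMGCS1 at 0.29 ± 0.14. ACADL, DGAT1 and SQLE had 1 sign on both arrays of 1 dye orientation and the opposite sign on both arrays of the other. By this criterion, 8 of the 60 named probes in all had opposite signs (also BID, AQP9, UHRF1, MYD88 and EIF1AY). In these 3 lists 0 members passed when adjusted over the list alone.

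Stress and energy lists had medians within 0.10 of 0. The 21 endoplasmic reticulum stress genes had a median of -0.06, with 13 lower, and DDIT3, a transcription factor of the unfolded protein response, had -0.43 ± 0.15 and the chaperone HSPA5 -0.17 ± 0.12. The 17 antioxidant genes had a median of -0.03, and catalase (CAT, -0.34 ± 0.13) and the mitochondrial superoxide dismutase SOD2 (-0.26 ± 0.12) were lower on all 4 arrays. The 16 heat shock and proteasome genes had a median of 0.09, with HSPB8 at 0.33 ± 0.13 and DNAJA1 at 0.28 ± 0.13. HSPB8 was above background in 1 of 4 control channels. The 14 apoptosis and p53 genes had a median of 0.06, with CASP6 at 0.33 ± 0.14 and BID at -0.29 ± 0.13. The 6 glycolysis genes had a median of -0.06, with TPI1 at -0.29 ± 0.13 and ENO1 at 0.17 ± 0.13. The 17 oxidative phosphorylation genes had a median of 0.01, with ATP5F1 at 0.32 ± 0.12 and COX7C at -0.19 ± 0.12. The adjusted p was 0.711 for oxidative phosphorylation and 0.678 for the other 5 of these lists, and 0 of their members passed when adjusted over the list alone.

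DNA methylation and chromatin genes did not pass as a shift in 1 direction, but passed a test for differences in either direction. Of 16 tested, 8 were higher and 8 lower, with a median of 0.00 and an adjusted p of 0.743 by camera. The mixed test of fry, which asks for differences in either direction, gave this list an adjusted p of 0.0380, the only list of 23 to pass it, and 0.297 without TET1. TET1 passed when adjusted over the list alone, at 0.0053. UHRF1, which recruits maintenance methylation to replicated DNA, had -0.32 ± 0.12 and was above background in 1 of 4 high NEFA and 4 of 4 control channels. Of 6 imprinted genes, 3 were lower and 3 higher, with a median of -0.04 (adjusted p 0.678). GRB10, an adaptor that inhibits insulin receptor signalling, was lower on all 4 arrays at -0.47 ± 0.13 and passed when adjusted over the list alone, at 0.0298, and had -0.15 ± 0.04 with mean pixel intensity. NNAT, above background in 1 of 4 control channels, had 0.26 ± 0.14. The 14 insulin and growth factor genes had a median of -0.05 (adjusted p 0.692), with RPS6KB1 at -0.24 ± 0.13, AKT2 at -0.23 ± 0.13 and 0 members past when adjusted over the list alone. RPS6KB1 was above background in 2 of 4 high NEFA and 3 of 4 control channels.

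Markers of other cells and the remaining lists did not pass. The 11 granulosa and cumulus cell genes had a median of -0.15 and a mean of -0.05 (adjusted p 0.678). The activin-binding protein follistatin (FST) had 0.42 ± 0.13, NPR2 -0.30 ± 0.14, the intermediate filament VIM 0.11 ± 0.30 and AMH 0.07 ± 0.14. The 11 oocyte genes had a median of -0.15 (adjusted p 0.678), with GDF9 at -0.33 ± 0.13, ZAR1 at 0.30 ± 0.13, MOS at -0.20 ± 0.24, and the zona pellucida genes ZP2 at 0.09 ± 0.13 and ZP4 at -0.23 ± 0.15. ZAR1 was above background in 1 of 4 control channels. The 1 sex-linked marker measured, EIF1AY, had 0.16 ± 0.14 (adjusted p 0.678 as a list). The 14 cell cycle genes had a median of 0.04, with CDC25C at -0.28 ± 0.13 and CDC20 at 0.32 ± 0.16, and the 35 ribosomal protein genes had a median of 0.02, with RPS26 at 0.29 ± 0.16 and RPL10L at 0.18 ± 0.12 (adjusted p 0.678 for both lists). Over the arrays, CDC20 ran from -0.15 to 0.69 and RPS26 from -0.15 to 0.76. In these 5 lists 0 members passed when adjusted over the list alone.

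**Figure D3:**
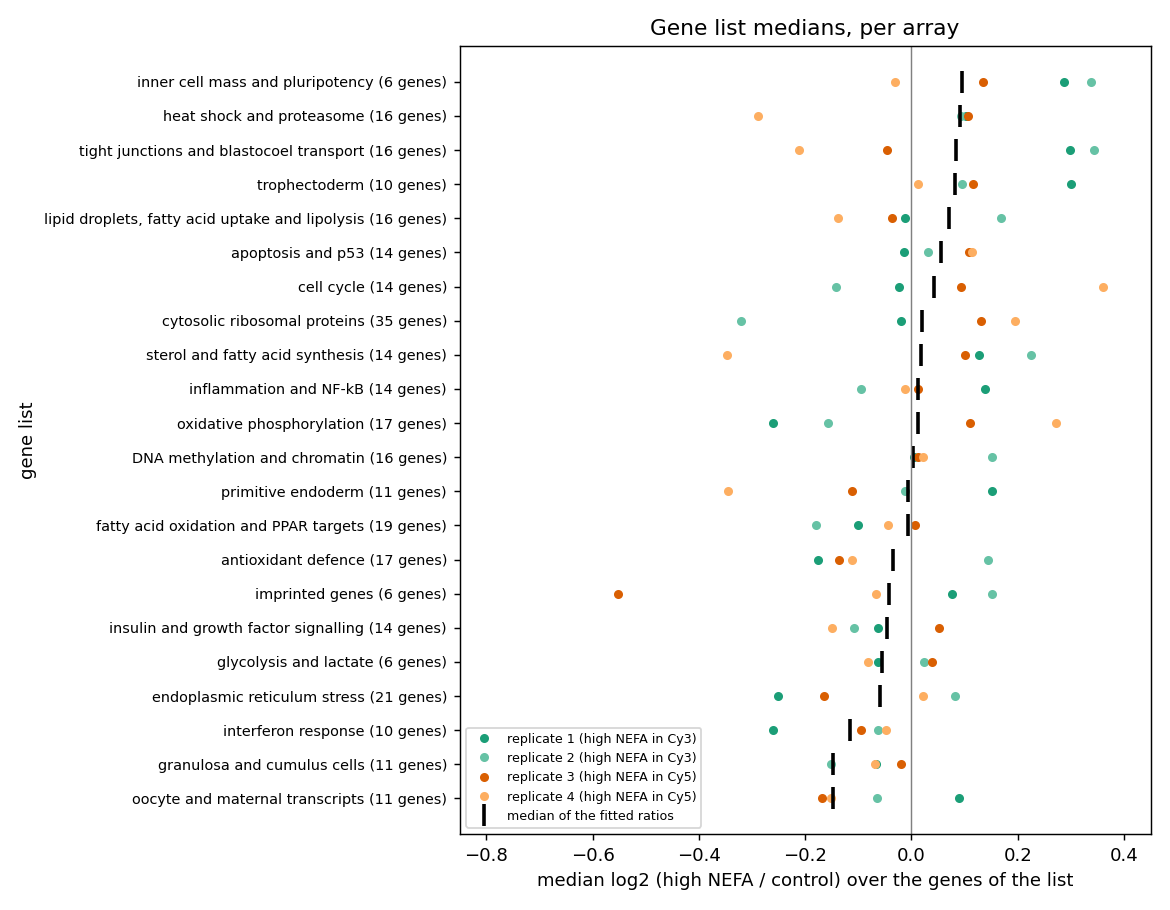
Median log2 ratio of high NEFA over control over the tested genes of each list with more than 1 tested gene, on each of the 4 arrays (points) and over the fitted ratios (bars). Fitted medians run from -0.15 for the oocyte list to 0.10 for the pluripotency list, and for most lists the arrays lie on both sides of 0.

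Arrays of opposite dye orientation did not move together. Over the 24524 tested probes, the correlation of log2 high NEFA over control was 0.46 between replicates 1 and 2 and 0.62 between replicates 3 and 4, but -0.51 on average between orientations (-0.51 to -0.50). Left as Cy5 over Cy3, all 6 pairs of arrays correlated between 0.46 and 0.62. These correlations are across probes, which are not independent replicates. The dye effect passed the adjusted threshold at 5603 probes (22.8%), and its SD over probes was 0.38 against 0.17 for the exposure ratio. Of 6226 genes, 471 (7.57%) had the same direction on all 4 arrays, where 1 in 8 would by chance without a dye effect. The direction of every ratio rests on the labelled dyes.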

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

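The tests of the 5 probes, of the dye pattern and of noise in the agreement between probes, and the counts over other splits, were chosen after the results were seen. The tests of the 88 probes and of local background in the agreement between probes were set before their values were seen, but after it was known that 28 probes passed the nominal threshold with no background correction, 27 of them among the 88.

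The 5 probes of smallest p, all with a positive fitted ratio at an adjusted p of 0.0934, are the first pattern. With 1 background per array and channel, 0 of the 5 kept over 50% of their log2 ratio, and their median ratio went from 1.09 to 0.08. Of the 88 probes past the nominal threshold, 36 (40.9%) remained past it, and 65.9% of the 88 had a local background over 100 in some channel, against 11.8% of tested probes. Local background estimates of single spots may therefore account for the 5 probes and for part of the 88, and an exposure effect on GNPDA2 or CEP250 transcripts finds no counterpart at their second probes, at -0.01 ± 0.13 and 0.05 ± 0.13. What raised the background around these spots in the control channels was not tested, and the ratios of TET1, CD109, OAS1, MED1 and ICAM1 moved by at most 0.06 with 1 background per array and channel but went to 0.50, 0.37, -0.65, -0.43 and -0.42 with mean pixel intensity.

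The negative correlation between arrays of opposite dye orientation is the second pattern, with a label error and dye bias of single probes as candidate explanations. For 1183 genes with 2 probes, the dye contrast correlated at only 0.13 between the probes of a gene (bootstrap 95% interval over genes 0.07 to 0.18), although it repeated between arrays at 0.46 to 0.62, which is what a dye bias of single probes would give. Were high NEFA and control in the same dyes on all 4 arrays, and this the whole cause, the 2 probes should correlate at least as well as in the 3 contrasts between pools, the labelled exposure included. With mean pixel intensity, a setting chosen after seeing the data, the dye contrast lay below all 3. The differences were -0.161 (interval -0.23 to -0.10) from the labelled exposure and -0.299 (-0.38 to -0.22) and -0.275 (-0.36 to -0.19) from the others. In that setting only, this argues against a label error as the whole cause. With median intensity the differences of 0.003 (-0.07 to 0.08), -0.119 (-0.20 to -0.04) and -0.066 (-0.15 to 0.02) do not decide. The difference from the labelled exposure was 0.023 (-0.05 to 0.10) with 1 background per array and channel. It was 0.018 (-0.06 to 0.10) with no background correction, and neither decides. The intervals cover genes, not pools. The covariance between probes was 0.018 (0.0095 to 0.026) for the dye contrast against 0.0035, 0.0058 and 0.0048 for those between pools (0.0137 against 0.0033 to 0.0043 with mean pixel intensity), as a label error in part would give, but dye bias from sequence that the probes of a gene share would give it too, and as the dye contrast holds both, a label error as part of the cause cannot be told apart.

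The third pattern is that the 2 probes of a gene agreed better in splits unrelated to exposure, although by count exposure had more probes at an unadjusted p under 0.05 (1573 against 973 and 1073). The 2 other splits are named here on ratios left as Cy5 over Cy3. Turned to high NEFA over control, the first sets replicates 2 and 3 against 1 and 4. The second then sets replicates 2 and 4 against 1 and 3. Between the 2 probes, the exposure contrast correlated at 0.12 (0.07 to 0.17), against 0.24 (0.18 to 0.30) for replicates 1 and 3 against 2 and 4 and 0.19 (0.12 to 0.26) for replicates 1 and 4 against 2 and 3. Measurement noise independent between the 2 probes would put the last value at 0, which its interval excludes. Errors that the probes of a gene share would not, and these were not tested. The 2 probes correlated at 0.69 in mean log2 intensity, and they can share sequence. Local background does not account for the order, since with 1 background per array and channel the exposure contrast stayed 0.08 below the lower of the other splits (difference -0.084, interval -0.165 to -0.0025), though with each spot's local background that interval included 0 (-0.15 to 0.01). Differences between pools, in embryos or in RNA handling, may be behind it, the smallest of 3 contrasts would be the exposure in 1 of 3 cases by chance, and no biological explanation was tested.

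Other ways of exchanging high NEFA and control within arrays, with the dye term kept, make 7 splits with the real one, which are too few for a share under 0.05. The real split gave 0 probes past the adjusted threshold, and the highest of the others 9. It gave 88 probes past the nominal threshold, and the highest of the others 204. It gave 0 gene lists, and the highest of the others 3. As large a nominal count came in 6 of the 7 splits. The highest counts of the others all came from splits that set a lone array against the rest. The real split does not, so those counts are not comparable with it. With real counts of 0 for the adjusted threshold and the lists, all 7 splits give as many by construction, and these comparisons show nothing. The other 2 splits that part the dyes evenly gave 77 and 108 nominal probes, and 973 and 1073 at an unadjusted p under 0.05, against 1573 for the real split. In the same order they gave 2 and 4 probes past the adjusted threshold, and 1 and 0 gene lists.

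Single arrays stood apart in 5 of 90 values tested. Chance gives 1 in 20 only where the 4 arrays differ by noise alone. The ratios tested still held the dye effect, which parts the arrays by orientation, so the count cannot be set against chance. HMGCS1 had a ratio of 0.68 on replicate 1, against 0.11 to 0.20 on the others. IL6ST had 1.12 on replicate 3, against 0.28 to 0.39. The DNA methylation and chromatin list had a median of 0.15 on replicate 2, against 0.00 to 0.02. The heat shock and proteasome list had a median of -0.29 on replicate 4, against 0.09 to 0.11. Replicate 1 had 60 spots marked to be ignored, against 17 to 21.

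Signal also appeared in control spots that enter no comparison. The 320 spike-in control spots named E1A had a median intensity of 21.1 to 54.9 times the negative control mean over the 8 channels. The 36 spots whose names begin with DCP had 20.6 to 40.9 times that mean.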

How the results depend on the processing

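Mean pixel intensity and 1 background per array and channel were chosen after seeing the data; the other alternatives were not. The cause was not tested where none is named. A block for slide or scan date was not run.

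The count past the adjusted threshold was 0 with no background correction, median centring, all 8 channels, no dye term, the trended robust prior, array weights, mean pixel intensity and 1 background per array. The count was also 0 with Aquantile, which left the log ratios as they were. It was 5 with plain subtraction, 4 with an offset of 16, 5 without a filter, 3 with the authors' matrix values and 5 at an adjusted p under 0.1. With 1 background per array and channel, all 9 different probes so called had under 50% of each log2 ratio they were called at, or another sign, and 7 of the 9 had so against their ratio at an offset of 50 with local background. With each replicate left out, 22 to 79 probes passed, 5 of them in all 4 fits, the 5 with an adjusted p of 0.0934 with all arrays. These fits leave a lone array in 1 orientation, assumed to vary like the others, and simulated arrays without effect gave 1.6 calls on average and 17 at most (9.15 and 29 with moderated variances).

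The nominal count of 88 became 28 with no background correction, 207 with an offset of 16, 43 with all 8 channels, 46 with no dye term, 18 with mean pixel intensity (16 higher, 2 lower) and 232 to 274 with a replicate left out. The number of lists past the threshold became 1 with plain subtraction (trophectoderm, adjusted p 0.0460), 1 with the authors' matrix values (trophectoderm, 0.0278) and 0 to 3 with a replicate left out. Without replicate 2 these were trophectoderm (0.0185), interferon response (0.0073) and ribosomal proteins (0.0185), without replicate 3 interferon response (0.0436) and without replicate 4 heat shock (0.0245). These calls use the preset correlation of 0.01. At an estimated correlation, run with all arrays only and on 2 residual degrees of freedom, these lists had 0.822 to 0.883. Over all alternatives the adjusted p of trophectoderm ran from 0.0185 to 0.822. The correlation between dye orientations, -0.51, was -0.52 with no background correction, -0.44 with plain subtraction, -0.52 with median centring, -0.52 without a filter, -0.49 with all 8 channels, -0.43 with the authors' matrix values, -0.66 with mean pixel intensity and -0.52 with 1 background per array.

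With mean pixel intensity the SD of log2 ratios over tested probes was 0.10 against 0.17, and 44 of the 60 named probes, most of them chosen by their p with median intensity, had under 2/3 of their ratio or another sign. Some values changed sign. With mean pixel intensity, DGAT1 was -0.032, DNAJB4 0.145, GNPDA2 -0.042, NNAT -0.028, SOX15 0.107, UHRF1 0.084 and ZP2 -0.024 (ERBB4, EMPV1_01763, CEP250 and JPH3 kept their sign, at 0.38 to 0.68), and the list medians were -0.011 for DNA methylation, -0.0036 for inflammation, 0.0035 for insulin, -0.0021 for lipid droplets and -0.028 for sterol synthesis. With median centring, the medians were -0.023 for ribosomal proteins, -0.0049 for oxidative phosphorylation and 0.017 for primitive endoderm. With the mean of all probes, they were -0.0038 for ribosomal proteins and 0.027 for imprinted genes. With all 8 channels, they were -0.039 for cell cycle, 0.068 for granulosa and -0.096 for inflammation. Without a filter, they were -0.0087 for DNA methylation, 0.032 for fatty acid oxidation and 0.0037 for glycolysis. The DNA methylation median was -0.0033 with plain subtraction and -0.0026 with the authors' matrix values, which gave 0.021 for fatty acid oxidation.

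With a replicate left out, AMH ran from -0.063 to 0.20, MOS from -0.52 to 0.13 and VIM from -0.41 to 0.63. List medians ran from -0.12 to 0.034 for antioxidants, -0.068 to 0.091 for ribosomal proteins, -0.081 to 0.032 for DNA methylation, -0.10 to 0.089 for endoplasmic reticulum stress, -0.075 to 0.0018 for glycolysis, -0.058 to 0.17 for heat shock, -0.29 to 0.13 for imprinted genes, -0.056 to 0.12 for inflammation, -0.041 to 0.082 for lipid droplets, -0.16 to 0.051 for oocyte genes, -0.056 to 0.014 for oxidative phosphorylation and -0.044 to 0.17 for sterol synthesis. Of the list medians over all alternatives, 391 kept their direction and side of the threshold, 7 came past it and 39 changed sign, and of the named gene ratios 952, 38 and 13. Some alternatives cannot change a ratio by construction, among them Aquantile scaling, the trended robust prior, these array weights and the threshold of 0.1. The counts that kept their direction are therefore no measure of robustness.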

Other observations

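Some genes differed widely between pools with no common direction in the high NEFA pools. They were chosen after their values were seen, as those with the largest residual SD among 3446 genes above background in all 8 channels with no local background over 100. PARM1, a mucin-like membrane protein, had log2 ratios of -1.29, 0.60, -0.47 and 1.91 on replicates 1 to 4, with a residual SD of 1.52 against a median of 0.24. PRNP, the prion protein gene, had -1.43, 1.49, 0.86 and 1.12. VIM, a filament of mesenchymal and granulosa cells that other cells also express, had -1.59, 0.49, 0.09 and 1.43. The cyclin-dependent kinase inhibitor CDKN1A had -0.95, 0.52, -0.10 and 1.79, CCNA1, the germline cyclin A, -1.57, -0.51, -0.15 and 2.10, and CCND2, a cyclin of the first gap phase, -1.70, 0.18, 0.01 and 0.68. OAS1, at -1.84 to -0.15, was also among the 15 most variable of these genes.

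Marker genes above background are given as counts, with no test between lists. Of all probes, 31.7% were above background in all 8 channels and 17.8% in none, and a gene counts by its probe above background in most channels. Of 17 trophectoderm genes on the array, 9 were above background in all 8 channels, among them GATA2, GATA3, TEAD4, TFAP2A, TFAP2C and ELF5, and 2 in no channel. Of 12 pluripotency genes, 3 were (LIN28A, MYC and UTF1) and 1 in no channel. Of 14 primitive endoderm genes, 8 were, among them GATA6, FOXA2 and PDGFRA, and 1 in no channel. Of 19 granulosa and cumulus genes, 5 were (AMH, DCN, FST, NPR2 and VIM) and 2 were above background in no channel. Of 19 oocyte genes, 4 were (GDF9, MOS, ZP2 and ZP4) and 3 in no channel. Of 24 fatty acid oxidation genes, 17 were above background in all 8 channels and 1 in none.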
